A study of Danio rerio with 4 samples.

How the data were processed

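Messenger RNA was profiled in whole zebrafish embryos (Danio rerio) injected with morpholinos, which are antisense oligomers that block the translation or the splicing of a target mRNA. Per the labels' protocols, an injection of 2 nl at the one-cell stage delivered either 8 ng of a control morpholino or 4 ng of an rbm14a and 4 ng of an rbm14b morpholino. All embryos also received 300 pg of GFP mRNA to mark the injection, and were raised in Holtfreter's solution. A library was made from each of 4 pools of 50 embryos, with 1 pool per morpholino treatment at 10 hours post fertilization (hpf) and 1 at 24 hpf. Per the labels' protocols, RNA was extracted with TRIzol, poly(A) RNA was selected on beads, and libraries were made with the NEBNext Ultra RNA kit. The labels do not say whether the rbm14 morpholinos block translation or splicing. Apoptosis is a known side effect of some morpholinos, and with no uninjected, rescue or further morpholino arm such an effect cannot be separated from that of losing Rbm14.

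The authors deposited TPM, a transcript abundance scaled to a fixed total per library, for each of 57596 Ensembl transcripts, with a gene symbol beside each. The unit was read from the values, which are not whole numbers and sum to 1000000 in each library. Per the submitters' processing notes, Trimmomatic 0.30, HISAT2 2.0.1, HTSeq 0.6.1 and the genome build GRCz10 were used, with no role stated for each. The tool that gave a value per transcript, the annotation release and the strand setting are not given in the sources used here. TPM divides by transcript length and by the library's total, so it keeps no sequencing depth. The depth of every library is therefore unknown, and no counting interval or detection limit was computed. A transcript listed at 0 may be a failed estimate, so no fold is given for a gene at 0 in a library.

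Transcript values were summed by symbol into 28697 genes, of which 14320 had more than 1 transcript. A symbol can merge several loci, as for the small RNAs U3, U5 and SNORA53, whose levels in poly(A) libraries are uncertain. Near-identical paralogs such as globins, crystallins and hsp70 genes are uncertain as well, because the authors' estimate may split reads between them. The reference table used here is of assembly GRCz12tu, which differs from the authors' build. It served only to match names and synonyms, and no genomic coordinates are given.

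With 1 library per group there is no replicate error, so no p-value was computed and each comparison describes the libraries compared. Comparisons were made between the rbm14 and control morpholino libraries at 10 hpf and at 24 hpf, and between the 24 and 10 hpf control libraries. Each pair was scaled by an unweighted trimmed mean of log2 ratios over genes with at least 1 TPM in both libraries, after trimming 30% of the ratios and 5% of the levels at each end. A pseudocount of 0.5 TPM was then added. Unless stated otherwise, folds are on this log2(TPM + 0.5) scale, which understates the difference for genes of low TPM. The subtracted shift, given as the log2 of the rbm14 over the control library, was −0.25 at 10 hpf and 0.64 at 24 hpf, and it was −0.52 for 24 over 10 hpf in the controls. Every ratio is relative to these shifts.

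A gene was past the size rule when its ratio was at least 2-fold (1 on the log2 scale) and its higher value was at least 5 TPM. The design fixed before the data were examined assumed read counts, with weighted trimmed-mean scaling and a 95% counting interval in the rule. Because the unit was TPM, its stated fallback on log2(TPM + 0.5) with no interval was used. Leaving out the weights was decided after the data were seen, since TPM gives no counts to weight by. The grouping, the rule, the gene lists and most alternatives were fixed before the data were examined.

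For each of 45 gene lists, the median log2 ratio was taken over members with at least 1 TPM in either library. It was set against the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The 2.5 to 97.5 percentile of these medians is called the random range, and lists under 5 measured members were given none. By construction 5% of random lists fall outside that range. Members of a gene list can vary together between single pools, so this share is no chance rate for a difference between treatments. The lists held 1076 named members, of which 993 matched the deposited symbols, 37 matched through a synonym and 46 did not match. Results for 1 of the lists and for 1 of its genes are not reported here, although the counts of lists, genes and alternatives include them.

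Genes were named by a fixed rule. It took the 10 highest and 10 lowest genes past the size rule in each knockdown comparison with a symbol not built from a clone or locus name, and 5 each for the stage comparison. It added up to 4 members per list by absolute ratio, 15 genes fixed in advance, and up to 10 genes past the rule in opposite directions at the stages. Genes were ranked by ratio in place of the bound of a counting interval. Where 5 or fewer members of a list were past the rule, those outside the naming rule were chosen after their values were seen, as were hsp70.1, hsp90aa1.2, mdm2, ccng1, aldoaa, pgk1 and the transcripts and genes named in the closing section.

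The steps were tested on simulated data with 200 genes altered among 28697 and a noise of 0.2 (SD, log2). Simulated shifts of 0.371, 0.354 and 0.307 for the 10 hpf, 24 hpf and stage comparisons came back as 0.364, 0.346 and 0.295. All 4-fold and 8-fold differences were recovered (100%) in each comparison. Simulated 2-fold differences, which lie on the threshold, were recovered at 48.5%, 44.8% and 47.8%, and 0.0437%, 0% and 0.0583% of unaltered genes passed. Of 60 unshifted lists 3.33% lay outside the random range, and 100% of 20 lists of 25 genes shifted by 0.5 were found in each comparison. The simulated noise was independent between genes and the lists were random, so none held genes that vary together. In the data, 668 genes at 10 hpf and 1446 at 24 hpf were past the rule. The 5 to 95 percentile of the 24 hpf log2 ratios was −1.29 to 1.14. The simulated rates therefore hold for that setting only. The alternatives were the deposited TPM without rescaling, median-of-ratios scaling, a loess curve, other TPM floors, another pseudocount, a larger fold, the most abundant transcript per gene and a filter on late genes. Those run for list medians drew fewer random lists than the reported setting. Their percentiles are therefore less exact, and a place close to an end of the random range is uncertain. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.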

Results

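The series asks how the RNA-binding protein Rbm14 takes part in setting up the dorsoventral axis of the zebrafish embryo. Zebrafish carry the paralogs rbm14a and rbm14b, and both were targeted together. Transcript levels were measured at 10 hpf, when gastrulation ends, and at 24 hpf, when the body plan and the early differentiated tissues are in place. There was 1 library of 50 pooled embryos for each morpholino treatment and stage, so none of the differences below has a replicate check. At 10 hpf the control library had 7120 genes at 5 TPM or more and the rbm14 library 6305, and at 24 hpf the control had 7000 and the rbm14 library 8866. Spearman's rho across 15757 genes, which are not independent replicates, was 0.958 between the 10 hpf libraries, 0.917 between the 24 hpf libraries and 0.644 between the control libraries of the stages.

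The targeted genes were expressed in all 4 libraries. Summed rbm14a stood at 170 TPM with the control and 254 TPM with the rbm14 morpholinos at 10 hpf (log2 ratio 0.83), and at 70.5 and 82.7 TPM at 24 hpf (−0.41). Summed rbm14b stood at 28.8 and 19.3 TPM at 10 hpf (−0.32) and at 21.0 and 28.2 TPM at 24 hpf (−0.21). Neither gene was past the 2-fold size rule at either stage, and without rescaling the 24 hpf ratios were 0.23 for rbm14a and 0.42 for rbm14b. A minor rbm14b transcript, ENSDART00000160709, was listed at 0.96 and 4.57 TPM at 10 hpf and at 0.12 and 4.55 TPM at 24 hpf. The main one, ENSDART00000172421, had 27.8 and 14.7 TPM at 10 hpf and 20.9 and 23.6 TPM at 24 hpf. Of rbm14a, ENSDART00000142071 had 25.7 and 62.5 TPM at 10 hpf and 7.79 and 19.9 TPM at 24 hpf. Another, ENSDART00000122073, had 11.3 and 4.53 TPM and then 5 and 3.56 TPM. Since a translation-blocking morpholino need not lower its target's mRNA, these levels neither check the labels nor measure the knockdown.

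At 10 hpf the question was which early patterning genes differ between the rbm14 and control morpholino libraries. Genes of the dorsal organizer, the signalling centre that specifies dorsal fate, were higher as a group in the rbm14 morpholino library, while the ventral and BMP pathway genes stood slightly below comparable genes. The genes lhx1a (14.8 and 39.4 TPM in the control and rbm14 libraries, 3.09-fold higher), the Nodal antagonist lft1 (60.7 and 124.7 TPM, 2.43-fold) and the BMP antagonist nog1 (45.0 and 89.9 TPM, 2.36-fold) were past the size rule. Germ plasm genes were also higher as a group, and so were oocyte genes except at a floor of 20 TPM. Lipoprotein and transport genes of the yolk syncytial layer, the tissue that transfers yolk to the embryo, were lower. Whether the 10 hpf pools differed in developmental stage was not tested. Between the control stages the organizer (−1.86), oocyte (−2.07) and germ cell (−1.54) lists fell and the yolk syncytial list rose (4.09). A younger rbm14 pool would give these directions. It would not give those of the ventral and BMP list, which fell (−0.75), or of the ribosomal protein list, which rose (2.198). Both of these 10 hpf differences were small, however. The ventral and BMP median was −0.10, and −0.01 with median-of-ratios. The ribosomal median of 0.43 lay just above its random range, and within it at a floor of 20 TPM. These lists therefore do not settle whether the rbm14 pool was younger.

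Of 19 measured dorsal organizer genes, 3 were past the rule as higher, none as lower, and 16 lay between. The list median was 0.64, against a random range of −0.06 to 0.42 (percentile 100), and 0.39 without rescaling. The organizer transcription factor gene gsc stood at 45.9 TPM in the control and 76.1 TPM in the rbm14 library (log2 ratio 0.97), and the BMP antagonist gene chordin, chd in the deposited symbols, at 84.5 and 106 TPM (0.57). A homeobox gene of low level, sebox, had 0.30 and 1.37 TPM (1.36). The Wnt antagonist gene dkk1b went the other way, with 88.4 and 49.3 TPM (−0.59). The genes gsc, chd, sebox and dkk1b were not past the rule.

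Of 33 ventral and BMP pathway genes, none was past the rule as higher, 1 was lower and 32 lay between. Their median was −0.10, below a random range of −0.04 to 0.34 (percentile 0.59), but it was −0.01 with median-of-ratios and 0.095 at a floor of 20 TPM, where the random lists rose as well (percentile 2.25). The lower gene was bambib, which encodes a BMP pseudoreceptor (5.30 and 1.14 TPM, 3.07-fold lower). The BMP target msx1b had 203 and 91.5 TPM (−0.89) and the epidermal regulator tp63 had 5.09 and 2.00 TPM (−0.95). The ligand bmp2b stood at 119.5 and 84.5 TPM (−0.25), bmp4 at 12.8 and 12.3 TPM (0.19), and the chordin-regulating gene szl at 72.0 and 45.5 TPM (−0.41). The ventral repressors of dorsal genes did not share a sign, with ratios of 0.92 for vox (646 and 1024 TPM), 0.58 for vent and −0.20 for ved. The ventral gene eve1 had a ratio of 0.05 and the mesodermal gene brachyury, ta in the deposited symbols, one of 0.63.

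**Figure D1:**
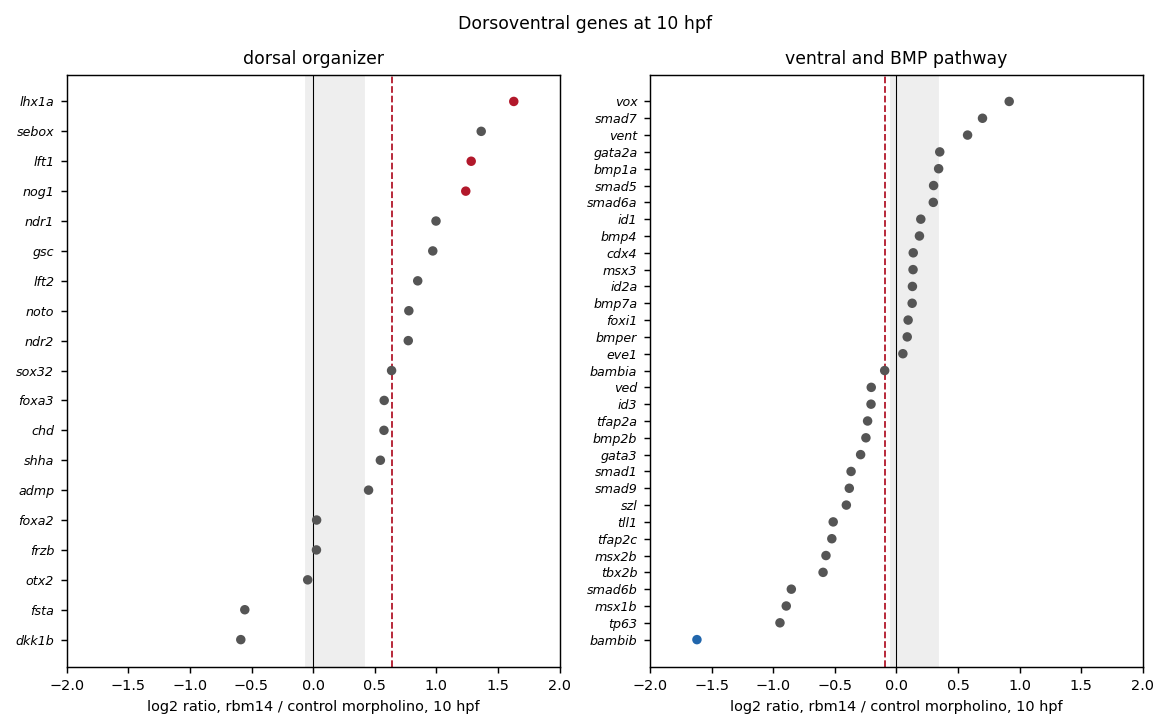
Log2 ratio of the rbm14 over the control morpholino library at 10 hpf (x axis) for each measured gene of the dorsal organizer list and of the ventral and BMP pathway list, 1 library per treatment. Red points are past the size rule as higher, blue as lower and grey are not past it, the dashed line is the list median (0.64 and −0.10) and the grey band is the 2.5 to 97.5 percentile range of medians of matched random lists.

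Further genes past the rule as higher at 10 hpf were the stress gene gadd45aa (3.50 and 9.36 TPM, 2.89-fold), the Akt inhibitor gene phlda3 (9.70 and 22.2 TPM, 2.63-fold), ccng1 (log2 ratio 1.09) and the pro-apoptotic gene bbc3 (4.22 and 7.57 TPM, 2.01-fold). The cell cycle inhibitor gene cdkn1a, not past the rule, stood at 6.66 and 8.36 TPM (0.54). Among 28 measured maternal oocyte genes 5 were higher, none lower and 23 between (median 0.33, percentile 99.62). The median was 0.08 without rescaling, and at a floor of 20 TPM the list lay within its range (percentile 87.12). The higher genes were the egg envelope gene zp3b (55.8 and 177 TPM, 3.76-fold), cldnd (3.38-fold), the oocyte kinase gene wee2 (3.29-fold), cth1 (1.46) and zgc:136254 (1.04). Of 13 germ cell and germ plasm genes 1 was higher and 12 lay between (median 0.66, percentile 100, and 0.38 with a pseudocount of 5). The higher gene was the piRNA pathway gene piwil1 (2.64 and 7.69 TPM, 3.04-fold), while the germ plasm organizer buc had 1.34 and 4.27 TPM (1.58).

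Yolk syncytial and lipoprotein genes had 26 measured members at 10 hpf, with 1 higher, 6 lower and 19 between, and a median of −0.69 (random range −0.15 to 0.32, percentile 0, and −0.25 with no TPM floor). The transferrin gene tfa stood at 128 and 24.7 TPM (4.303-fold lower) and the apolipoprotein gene apoba at 5.16 and 1.14 TPM (2.999-fold lower). The higher gene was mxtx2, a regulator of the yolk syncytial layer (0.61 and 9.99 TPM, 10.8-fold). Of 21 genes for cathepsins and lysosomal proteins, 1 was lower, cd63 (2.76-fold), and 20 lay between (median −0.18, percentile 1.71), and with loess the list lay within its range (percentile 3.1). The 75 ribosomal protein genes had a median of 0.43, just above a random range of 0.27 to 0.42 (percentile 97.91), and none was past the rule. The median was 0.17 without rescaling and 0.089 with loess. The list lay within its range at a floor of 20 TPM (percentile 97.45) and with the most abundant transcript per gene (percentile 90.95). The 233 numbered zinc finger genes, with 6 higher, 9 lower and 218 between, had a median of −0.08 at percentile 97.75, and this median was −0.31 without rescaling, 0.0015 with median-of-ratios and 0.064 with loess. The list lay within its range under every alternative run for list medians except median-of-ratios scaling.

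Of 7321 genes measured at 10 hpf, 668 were past the size rule, 261 as higher and 407 as lower (39.1% higher). Among named genes, the cyclin gene ccna1 was the highest (6.68 and 205 TPM, 33.9-fold), followed by mxtx2, the blood and vessel regulator lmo2 (0.36 and 6.70 TPM, 9.41-fold), hid1a (8.17-fold) and ecm1b (7.44-fold). SNORA53, U3, rxfp3.3a1, U5 and SNORA23 were listed at 0 in the control and at 5.21 to 9.69 TPM in the rbm14 library. The lowest were eml1 (8.45 and 0.40 TPM, 8.80-fold lower), the embryonic globin gene hbbe1.1 (5.22 and 0.10 TPM, 8.68-fold), SCARNA2 (7.58-fold), znf1060 (6.38-fold), CAMK2N1 (6.22-fold) and P2RY6 (5.78-fold). They were followed by the clock gene bhlhe41 (5.64-fold), dnajb9b (5.34-fold), il1rl1 (5.02-fold) and the hypoxia-responsive gene igfbp1a (4.90-fold). The low 10 hpf reading of hbbe1.1 was 0.230% of its 24 hpf TPM in the controls. The split depends on the scaling, with 155 higher and 676 lower (18.7% higher) without rescaling and 320 higher and 329 lower (49.3%) with median-of-ratios. Of 42 lists with a random range, 6 stood above it and 3 below.

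At 24 hpf the comparison asks how the same treatment differs from its control once tissues have differentiated. In the rbm14 morpholino library the cell cycle inhibitor gene cdkn1a was higher (7.88 and 151 TPM in the control and rbm14 libraries, 11.8-fold), with the pro-apoptotic gene bbc3 at 0.93 and 29.0 TPM (14.3-fold). Genes of lens, muscle, blood, pigment cells and yolk syncytial layer were lower as groups, as were ribosomal protein and cell cycle genes, and most of these medians lay nearer to 0 without rescaling. The embryonic globin gene hbbe1.1 stood at 2266 and 98.9 TPM (35.5-fold lower). Its paralog hbbe1.2 stood at 245 and 435 TPM and hbbe3 at 4316 and 1622 TPM, and reads may be split between such paralogs.

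Among the higher genes at 24 hpf, the ubiquitin-like modifier gene isg15 stood at 0.43 and 99.4 TPM (77.3-fold), phlda3 at 8.23 and 222 TPM (16.6-fold), gadd45aa at 2.66 and 72.8 TPM (15.4-fold) and the transcription factor gene foxo3b at 1.27 and 30.4 TPM (11.9-fold). The ubiquitin ligase gene mdm2 had 25.6 and 416 TPM (10.3-fold) and ccng1 had 247 and 2892 TPM (7.49-fold). Of 21 genes of the unfolded protein and heat shock response, 7 were higher, none lower and 14 between (median 0.33, percentile 99.89). The median was 0.97 without rescaling and 0.67 with loess, and at a floor of 20 TPM the list lay within its range (percentile 96.25). Most of the higher genes encode cytosolic chaperones, among them hsp70.3 (17.8 and 250 TPM, 8.81-fold), hsp70l (7.23-fold), hsp70.2 (6.19-fold), hsp70.1 (1.40) and hsp90aa1.2 (1.42), and the stress transcription factor gene atf3 was 3.72-fold higher.

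Markers of differentiated tissues were lower at 24 hpf in several lists. All 9 lens crystallin list genes past the rule were lower among 18 measured, with 9 between (median −1.99, random range −0.18 to 0.57, percentile 0, and −0.63 with a pseudocount of 5). They included crybb1 (13.6 and 1.0 TPM, 13.4-fold lower), cryba1l1 (12.7-fold) and cryba1b (12.3-fold). Of 59 muscle structure genes, 26 were lower, 1 was higher and 32 lay between (median −0.94, percentile 0, and −0.30 without rescaling). The calcium buffer genes pvalb1 (33.2 and 2.26 TPM, 18.1-fold lower) and pvalb4 (13.6-fold) and the troponin gene tnni2a.4 (11.7-fold) were the lowest, and the higher gene was obscnb (2.16). Of 39 erythroid genes, 13 were lower and 26 lay between (median −0.84, percentile 0, and −0.21 without rescaling), with hbbe1.1, hbae1 (102 and 12.8 TPM, 11.9-fold lower) and hbbe2 (7.53-fold) among the lowest. The 12 myeloid genes had 3 lower and 9 between (median −0.74, percentile 0.14, and −0.20 without rescaling), namely the neutrophil genes mpx (5.65 and 0.31 TPM, 10.1-fold) and lyz (8.29-fold) and the regulator cebpb (−1.06).

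Neural crest and pigment genes had 10 lower and 21 between among 31 measured (median −0.90, percentile 0, and −0.47 without rescaling), but lay within the range at a floor of 20 TPM (percentile 2.85). The melanin synthesis gene tyrp1b (12.1 and 1.57 TPM, 8.87-fold lower) and the pteridine synthesis gene gch2 (88.5 and 15.7 TPM, 8.49-fold) led them. Of 33 yolk syncytial and lipoprotein genes, 14 were lower, 3 higher and 16 between (median −0.88, percentile 0). The median was −0.24 without rescaling and −0.23 with loess, and at a floor of 20 TPM the list lay within its range (percentile 10). Among its members apoa4b.3 (9.33-fold lower), apoea (7.19-fold) and tfa (471 and 115 TPM, 6.36-fold) were the lowest and hnf4a (1.18), slc26a1 (1.36) and dgat2 (1.04) were higher. Of 38 collagen genes, 9 were lower, 1 higher and 28 between (median −0.66, percentile 0, and −0.06 without rescaling), with col5a3b (3.37-fold) and col1a1b (3.35-fold) the lowest and col7a1l (2.14-fold) the higher one. Of 28 neuronal differentiation genes, 7 were lower, 1 higher and 20 between (median −0.57, percentile 0), but the median was 0.021 without rescaling. The proneural genes atoh1a (48.7 and 15.9 TPM, 4.64-fold) and ascl1b (3.95-fold) were lower and the neuronal RNA-binding gene elavl3 (1.06) was higher.

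Ribosomal protein genes took 17.4% of all TPM in the 24 hpf control library and 11.1% in the rbm14 library. Of 75 measured, 64 were lower, none higher and 11 between (median −1.25, random range −0.70 to −0.32, percentile 0, and −0.61 without rescaling or −0.46 with loess). The largest differences were those of rps9 (10079 and 3526 TPM, 4.45-fold lower), rps29 (3.71-fold) and rps20 (3.65-fold). Of 44 cell cycle genes 12 were lower and 32 between (median −0.73, percentile 0, and −0.096 without rescaling), led by the replication gene mcm7 (679 and 383 TPM, 2.76-fold) and kpna2 (2.67-fold). The 17 maternal oocyte genes had 4 lower and 13 between (median −1.03, percentile 0, and −0.48 without rescaling or −0.25 with a pseudocount of 5), namely zp3.2 (−1.06) and the cell cycle genes ccnb1 (−1.18), ccnb2 (−1.13) and fbxo5 (−1.10). Of 14 histone genes 4 were lower and 10 between (median −0.92, percentile 0.59, and −0.28 without rescaling). The list lay within its range with loess (−0.34, percentile 3.2) and at a floor of 20 TPM (percentile 6.4). The lower genes were h1f0 (2935 and 1763 TPM, 2.59-fold), h2afvb (2.31-fold), h1fx (2.29-fold) and h3f3a (−1.08). Of 19 ubiquitous reference genes 8 were lower and 11 between, with a median of −0.61 that lay within the random range (percentile 5.69) and was 0.022 without rescaling. This list stood below its range with the most abundant transcript per gene (percentile 0.15). All 13 mitochondrially encoded genes had ratios below 0, with 1 past the rule, and their median of −0.55 was also within the range (percentile 43.2), and it was 0.094 without rescaling and 0.36 with loess.

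Genes of hypoxia and glycolysis were also lower as a group. Of 26 measured members 8 were lower, 1 higher and 17 between (median −0.76, percentile 0, and −0.16 without rescaling). The lactate dehydrogenase gene ldha (33.2 and 16.1 TPM, 3.14-fold), aldoaa (−1.25) and pgk1 (−1.25) were lower, and the glucose transporter gene slc2a1a (8.66 and 40.9 TPM, 2.94-fold) was higher. Of 79 oxidative phosphorylation genes 8 were lower and 71 between, with a median of −0.59 (percentile 0) that was 0.035 without rescaling. Among them cox6b1 (82.6 and 14.1 TPM, 8.81-fold) and ndufa4 (5.95-fold) were the lowest. Epidermis and periderm genes had 40 measured members, 2 higher, 8 lower and 30 between. Their median of −0.03 was at percentile 97.74, and it was 0.61 without rescaling and 0.47 with loess, while with no TPM floor the list lay within its range (percentile 95.25). Here the keratin genes krt18 (965 and 4439 TPM, 2.95-fold) and krt97 (2.51-fold) were higher and the fin fold gene and1 (9.42-fold) and krtt1c19e (7.06-fold) were lower.

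The dorsoventral lists lay within their random ranges at 24 hpf. Of 15 dorsal organizer genes 1 was higher, the activin antagonist gene fsta (55.7 and 233 TPM, 2.67-fold), and 14 lay between (median 0.35, percentile 96.7), although with the most abundant transcript per gene the median was 0.45 (percentile 99.1). It was 0.92 without rescaling and 0.11 with loess. The 32 ventral and BMP genes had 2 higher, cdx4 (20.5 and 93.9 TPM, 2.90-fold) and foxi1 (2.07-fold), none lower and 30 between. Their median was 0.04 (percentile 78.72), and −0.02 with median-of-ratios, 0.67 without rescaling and 0.18 with loess. Values of bmp2b were 12.7 and 31.9 TPM (0.67) and of bmp4 4.2 and 8.09 TPM (0.28). Whether the dorsal or ventral groups differ between the stages was not tested.

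Of 9121 genes measured at 24 hpf, 1446 were past the size rule, 639 as higher and 807 as lower (44.2% higher). Besides isg15, phlda3, gadd45aa, bbc3, foxo3b and cdkn1a, the highest named genes were the immediate early gene fosab (4.41 and 167 TPM, 22.4-fold), atxn1b (17.1-fold), the retinoblastoma family gene rbl2 (17.0-fold) and nnr, listed at 0 in the control and at 7.66 TPM in the rbm14 library. The lowest besides those above were aep1 (126 and 8.32 TPM, 22.0-fold lower), the posterior gene hoxb13a (16.5-fold), crybb1l2 (13.9-fold), the pteridine synthesis gene sprb (13.6-fold) and crybb1l1 (13.1-fold). The split again depends on the scaling, since 2460 genes were higher and 250 lower without rescaling (90.8% higher). Of 45 lists, 3 stood above the random range and 14 below. The 5% of random lists outside it is no chance rate for lists whose members vary together.

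**Figure D2:**
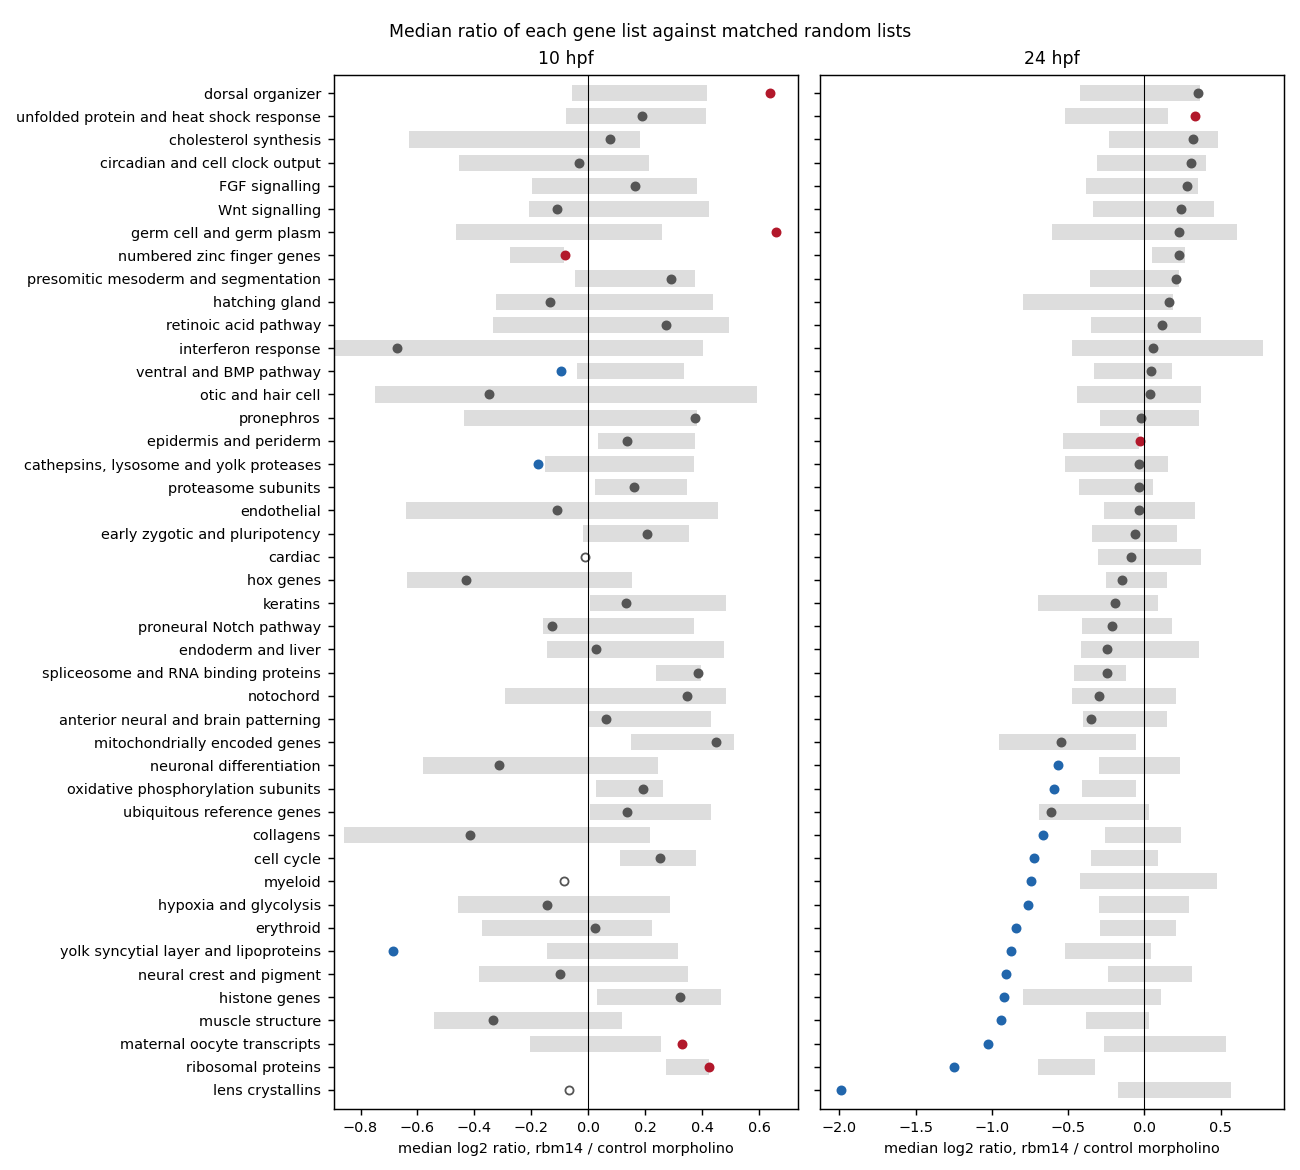
Median log2 ratio of the rbm14 over the control morpholino library (x axis) for each of 44 gene lists at 10 hpf and 24 hpf, ordered by the 24 hpf median, 1 library per treatment and stage. Grey bars are the 2.5 to 97.5 percentile range of medians of 10000 matched random lists, red points lie above it, blue points below it and grey points within it, and open points are lists with under 5 measured members, which have no range. The dorsal organizer list lies above the range at 10 hpf (0.64), and some medians near 0 change sign with the scaling.

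The pairs of libraries at 10 and 24 hpf share no library, and 6389 genes were measured in both. Higher at both stages were 31 genes, where independent lists of these sizes would share 8.87. They included gadd45aa, phlda3, ccng1 and bbc3, as well as fosab and the sterol synthesis gene cyp51 (1.85 at 10 hpf and 1.61 at 24 hpf). Lower at both were 47 genes, where independent lists would share 19.4. Among these were the tubulin genes tuba1b (−1.58 and −2.49) and tubb5 (−2.18 and −1.17), the Notch target genes her15.1 (−2.11 and −1.05) and her15.2 (−1.29 and −1.71), tfa (−2.11 and −2.67), h1f0 (−1.09 and −1.38) and SCARNA2 (25.96 and 2.48 TPM at 10 hpf, 17.1 and 2.79 TPM at 24 hpf). Opposite directions were found for 11 genes higher at 10 hpf and lower at 24 hpf (10.0 for independent lists) and for 11 of the reverse kind (17.1). Across genes, which are not independent replicates, the log2 ratios of the stages had a Pearson r of 0.134 and a Spearman rho of 0.0705, and 52.3% shared a sign.

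Between the control libraries, the stage comparison gives the size of the differences between 1 pool per stage injected with the control morpholino. Muscle genes were higher at 24 hpf as a group, with 51 of 59 past the rule and none lower (median 6.40, percentile 100). The cardiac and skeletal actin gene actc1b went from 6.55 to 3907 TPM (785-fold higher), the creatine kinase gene ckmb from 6.50 to 3849 TPM (779-fold), the hatching enzyme gene he1a from 16.0 to 7916 TPM (685-fold), the calcium pump gene atp2a1 from 3.11 to 1745 TPM (676-fold) and the globin gene hbbe3 from 9.66 to 4316 TPM (605-fold). For actc1b, ckmb, he1a, atp2a1 and hbbe3 the 10 hpf reading was 0.168%, 0.169%, 0.202%, 0.178% and 0.224% of the 24 hpf one. If such readings come from carry-over between libraries, these folds are lower bounds. Of 48 hox genes 47 were higher and 1 lay between (median 4.67). Notochord (5.03), neuronal (4.12), yolk syncytial (4.09) and collagen (3.76) genes were higher as well. All 75 ribosomal protein genes were higher (median 2.198).

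Early regulators were lower at 24 hpf. The endoderm gene sox32 went from 360 to 0.48 TPM (280-fold lower), the pluripotency gene pou5f3 from 1240 to 4.25 TPM (185-fold), vrtn from 497 to 2.1 TPM (138-fold) and the Wnt antagonist gene frzb from 92.3 to 0.26 TPM (95.5-fold), while nnr stood at 647 TPM and was then listed at 0. Of 28 maternal oocyte genes 16 were lower and 12 between (median −2.07), and of 19 dorsal organizer genes 14 were lower, 3 higher and 2 between (median −1.86). Wnt signalling (−1.81), early zygotic (−1.71), germ cell (−1.54), spliceosome (−1.09) and ventral and BMP genes (−0.75) also lay below their random ranges. Of 8784 genes measured, 4629 were past the rule, 2599 as higher and 2030 as lower (56.2% higher). The split was 2029 and 3282 without rescaling (38.2% higher) and 2117 and 3053 with median-of-ratios (41.0%). Of 45 lists 24 stood above and 10 below the random range, and 13 of these came within it at a floor of 20 TPM.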

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

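Of the tests in this part, those of delay for the ribosomal proteins and both carry-over tests, and the bound used for short transcripts, were chosen only after the result was seen. Several results were picked out because the rbm14 and control libraries differed in opposite directions at the stages. The differences between stages were not tested, since there is 1 library per group. Each value here is the 24 hpf log2 ratio minus that at 10 hpf. The transcription factor gene eomesa was higher at 10 hpf (1.95) and lower at 24 hpf (−2.17), a difference of −4.12. The same order held for s100t (−3.98), gpr19 (−2.81) and slc16a3 (−2.49). The secretory cell regulator bhlha15 was lower at 10 hpf (−1.06) and higher at 24 hpf (3.38), a difference of 4.44. That order was shared by socs5a (2.86), C9orf69 (2.53), angptl4 (2.38), chdh (2.23) and fam46ba (2.12). These stand among 22 opposite genes, where independent lists would give 10.0 and 17.1 for the pair of orders. Among lists above the random range at 10 hpf and below it at 24 hpf were the maternal oocyte transcripts, whose median differed by −1.36 (−0.56 without rescaling), and the ribosomal proteins, which differed by −1.67 (−0.78 without rescaling and −0.54 with loess).

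Ribosomal protein genes at 24 hpf had a median of −1.25. Scaling as the whole cause is argued against by the loess curve alone. With it the median was −0.46, the highest over the 4 scalings, and stayed below the random lists (percentile 0). The other scalings differ by nearly the same shift for every gene. They could therefore hardly move this list against its random lists. A loss of short transcripts in this library as the whole cause is argued against, since 61 short transcripts outside the ribosome had a median of −0.34 (quartiles −0.66 and −0.02) and so lay above the upper quartile of the ribosomal genes (−1.09). The bound set beforehand also asked the long mRNAs of the translation machinery for a median below −0.5, and it was −0.43. That part was set aside, because losing short transcripts fixes no level for long ones. A smaller loss as part of the cause was not tested, and no transcript lengths were used. A delay of development also stays open, because the ribosomal protein share in the rbm14 library (11.1%) lay between those of the 10 hpf (5.604%) and 24 hpf (17.4%) controls. An effect of Rbm14 on these transcripts is a further explanation the design names, and it was not tested.

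Genes of differentiated muscle and blood were read at low TPM at 10 hpf. From the muscle, erythroid and lens lists, 31 genes had at least 100 TPM in the 24 hpf control and a control stage log2 ratio of at least 4. This rule by itself keeps the 10 hpf share low. For these genes the 10 hpf control held a median of 0.230% of the 24 hpf TPM (quartiles 0.186% and 0.347%) and the rbm14 libraries 0.201%. Carry-over of the control 24 hpf library into both 10 hpf libraries as the whole source is argued against. Whatever the shares, it would give all genes the same 10 hpf ratio. The knockdown ratios in this paragraph used deposited TPM with a pseudocount of 0.1. Among the 8 genes with at least 5 TPM in the 10 hpf control, however, the log2 ratios ran from −4.73 to 0.09. They followed those at 24 hpf (Spearman rho 0.905). A small carry-over of the same morpholino's 24 hpf library into its 10 hpf library is consistent with the values, since the 10 and 24 hpf ratios followed each other across genes (Spearman rho 0.744 over the 31 genes, 95% bootstrap interval over genes 0.52 to 0.88). Early transcription of these genes at 10 hpf, altered as at 24 hpf, was not tested and stays open.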

How the results depend on the processing

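No paired analysis was possible within a stage because there is 1 library per group, and a fit across the stages was not run. An alternative fixed in the design, the whole 95% counting interval beyond 2-fold, was not run, since TPM gives no counts, and the unknown depth leaves the counting error of every gene open. The most abundant transcript per gene, the filter on late genes and the unweighted trimmed mean were chosen after the data were seen. Over all alternatives, 62 counts of genes or shares of higher genes stayed near the reported value and 70 did not. For counts, near meant within 1.5 times the reported value. For shares it meant within 10 percentage points. Among list medians 837 kept their place against the random range, 35 lost it and 24 gained one. Of ratios of single genes, 2524 were classed as unchanged, 173 dropped out of the rule and 46 entered it. A further 216 that were not past it moved, and 1 that was past it reversed. Genes past the rule were unchanged if they kept their direction and stayed past it. Other genes were unchanged if they stayed outside it and moved by no more than the comparison's median absolute log2 ratio. The sign of those other genes was not checked. Under every alternative run for list medians, the dorsal organizer list stayed above its range at 10 hpf, with medians of 0.39 to 0.72.

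Without rescaling, 155 genes were higher and 676 lower at 10 hpf, and 2710 were past the rule at 24 hpf, with 2460 higher and 250 lower. In the stage comparison 3282 were lower, and 109 genes went in opposite directions at the stages. The 24 hpf ratio was 0.23 for rbm14a and 0.42 for rbm14b. These follow from leaving out the shift. The numbered zinc finger list at 10 hpf had a median of −0.31 (percentile 96.88). With median-of-ratios scaling, 3053 genes were lower in the stage comparison. With loess, list medians no longer outside the range were cathepsins at 10 hpf (−0.20, percentile 3.1), numbered zinc fingers at 10 hpf (0.064, percentile 81.2) and histones at 24 hpf (−0.34, percentile 3.2). The ratio of eef1a1l1 at 24 hpf reversed to 0.034. For these loess and median-of-ratios values the cause was not tested.

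Lower TPM floors pass more genes by construction. With no floor, 1792 genes were past the rule at 10 hpf (612 higher, 1180 lower), 2833 at 24 hpf (1347 and 1486) and 8520 between the control stages, of which 5709 were higher. Then 275 genes went the same way at both stages and 117 opposite ways, and the medians of the zinc finger list at 10 hpf (−0.081, percentile 79.58) and the epidermis list at 24 hpf (−0.030, percentile 95.25) lay within their ranges. At a floor of 1 TPM the counts were 1514 (501 and 1013) at 10 hpf, 2558 (1258 and 1300) at 24 hpf and 7537 between stages, 4834 of them higher, with 228 genes the same way and 82 opposite. At a floor of 20 TPM they were 198 (112 and 86), 666 (217 and 449) and 2369 (1178 and 1191), with 22 the same way and 4 opposite. With that floor, which also left fewer members, several lists came within range, among them 13 of the stage comparison. At 10 hpf they were maternal oocyte (0.33, percentile 87.12), ribosomal (0.43, percentile 97.45) and zinc finger genes (0.070, percentile 18.25). At 24 hpf they were the unfolded protein and heat shock (0.16, percentile 96.25), neural crest (−0.52, percentile 2.85), yolk syncytial (−0.72, percentile 10.0) and histone lists (−0.92, percentile 6.4).

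A pseudocount of 5 shrinks the ratios of low genes. It gave 218 genes at 10 hpf (125 higher, 93 lower), 697 at 24 hpf (193 and 504) and 1246 lower between stages, with 28 the same way, 3 opposite, and the zinc finger list at −0.047 (percentile 93.67). A 4-fold rule gave 81 (37 and 44), 233 (105 and 128) and 2227 (1600 and 627), with 5 the same way and 0 opposite. With the most abundant transcript per gene, the 10 hpf medians of ribosomal proteins (0.39, percentile 90.95) and zinc finger genes (−0.083, percentile 96.65) lay within range, and the cause was not tested. Without genes whose 10 hpf TPM was under 1% of the same arm's 24 hpf TPM, 651 genes were past the rule at 10 hpf (257 and 394), 76 went the same way at both stages and 21 opposite.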

Other observations

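Of the tests in this part, those of delay for the gene groups that fall between the stages and of noise in the shared control library, and the bound used for delay in the rising groups, were chosen only after the result was seen. Several groups within their random ranges held members past the size rule. At 24 hpf the 3 lower hox genes were hoxb13a (23.1 and 1.59 TPM in the control and rbm14 libraries), hoxa13a (17.6 and 8.77 TPM) and hoxc13a (14.9 and 7.67 TPM). The other 44 of 48 measured hox genes lay between, and hoxa11a (2.14-fold) was higher. Among 27 Notch pathway genes, 5 were lower at 24 hpf, namely her4.1, her4.2, her4.3 (9.14 and 2.31 TPM), her15.1 and her15.2, and hey1 (1.14) was higher. That list fell below its range with loess (percentile 1.9) and with the most abundant transcript per gene (percentile 1.325). Of 24 presomitic mesoderm and segmentation genes at 24 hpf, 3 were higher, namely her7 (6.93 and 26.0 TPM), tbx16 (1.93 and 7.08 TPM) and pcdh8 (2.05-fold), and 21 lay between (percentile 96.12). With no TPM floor this list stood above its range (median 0.26, percentile 98.75). Of 14 Wnt signalling genes tbx16 and wnt8a (2.13 and 11.6 TPM) were higher and 12 lay between (percentile 80.54).

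Interferon response genes included isg15 and ifit8 (0.12 and 7.55 TPM) as higher and b2m (10.1 and 3.83 TPM) as lower at 24 hpf, while the list median of 0.05 was at percentile 31.09, and it was 0.54 without rescaling and −0.13 with loess. In the cholesterol synthesis list cyp51 was higher at both stages, and sqlea (1.55 and 5.71 TPM) at 24 hpf. Early zygotic genes had 4 higher members at 10 hpf, which were mxtx2, eomesa (2.16 and 8.31 TPM), gdf3 (15.09 and 40.7 TPM) and mixl1 (5.27 and 9.78 TPM), with the list median at percentile 62.07. The proneural gene neurog1 (28.9 and 8.18 TPM) and the neural crest genes sox9a (17.1 and 5.52 TPM) and snai1b (5.29 and 1.72 TPM) were lower at 10 hpf.

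Genes with larger increases between the control stages tended to be lower in the rbm14 library at 24 hpf. Genes over 16-fold higher at 24 than at 10 hpf in the controls had a median knockdown log2 ratio of −0.70 (693 genes, 83.3% below 0), and genes over 16-fold lower had one of 0.35 (110 genes). The slope of the knockdown ratio on the stage ratio was −0.15 across 8784 genes, which are not independent replicates. These ratios share the 24 hpf control library, whose noise alone would give a negative slope. On a stage ratio that shares the rbm14 library instead, where such noise acts upward, the slope was −0.033 (95% bootstrap interval over genes −0.043 to −0.023). This cannot exclude noise as the whole cause, because genes were kept by their level in the control libraries, including that of 24 hpf. Genes that enter through a high reading there have lower knockdown ratios, which can itself make the slope negative.

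The hypothesis of one uniform delay of development was set against the lists. Of 18 lists that rose at least 4-fold between the control stages, 10 stood below their random ranges. The number with a knockdown median below 0 depends on the scaling, with 16 as reported and with loess, 17 with median-of-ratios and 9 without rescaling. The hatching gland, otic and keratin lists, 3 of the 18, lay above the middle of their random lists but within the range. The hatching gland list passed its range at a floor of 20 TPM (percentile 98.15) and with the most abundant transcript per gene (percentile 97.55), and the keratin list did so with loess (median 0.75, percentile 100). The bound set beforehand, at least 3 rising lists above the middle, was met. It was set aside because with the reported settings none of the 3 stood above its range and the otic (percentile 55.49) and keratin (percentile 68.92) lists lay near the middle, as chance can give. For the rising groups a delay therefore cannot be told apart from separate effects on tissues. Of 10 lists that fell between the control stages, 6 had a knockdown median above 0 as reported and with loess, 5 with median-of-ratios and 8 without rescaling. The dorsal organizer (percentile 96.7) and presomitic mesoderm (percentile 96.12) lists lay near the top of their ranges, as a delay would give. No falling list stood above its range with the reported settings. The organizer list did so with the most abundant transcript per gene (percentile 99.1), and the presomitic list with no TPM floor (percentile 98.75). A uniform delay as the whole cause is argued against for the falling groups, since it would leave them all high, yet 2 of the 10, the maternal oocyte (−1.03) and cell cycle (−0.73) lists, stood below their random lists. These share ccnb1 and ccnb2. A delay may therefore account for only part of the pattern, and an effect of Rbm14 on particular tissues was not tested.

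A further hypothesis was that the knockdown shifts the share of transcripts within genes alike at both stages, since Rbm14 binds RNA. Among 3047 genes, the main transcript's share differed by at least 20 percentage points in 149 genes at 10 hpf and 276 at 24 hpf. It did so at both stages in 47 genes, against 13.5 for independent lists, in the same direction in 30 and in opposite directions in 17. The prediction of at least 2 times as many genes in the same direction was not met and its opposite was not either, so the hypothesis cannot be told apart from errors in estimating transcript levels. The largest shared difference was in npm1a, whose transcript ENSDART00000133304 took 4.62% and 98.1% of the gene's TPM in the control and rbm14 libraries at 10 hpf and 7.86% and 99.8% at 24 hpf. In oaz1b, ENSDART00000160956 took 99.97% and 18.4% at 10 hpf and 99.9% and 25.4% at 24 hpf.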
